A study of Schizosaccharomyces pombe with 70 samples.

How the data were processed

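The deposited values were log2 ratios of the Cy5 to the Cy3 channel, per the labels. Cy5 carried cDNA of the sample (treated, or untreated at 0 min) and Cy3 cDNA of untreated wild type, both labelled through aminoallyl-dUTP. The base of the logarithm and the direction were settled from the values: 100% were log2 of a ratio with 3 decimals, within a relative tolerance of 1e-05, and deleted genes were low in their own mutants. The normalization behind the values is not given in the sources used here. No further scaling was applied. All 70 arrays were used. Array medians lay between -0.15 and 0.06.

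Each gene feature had 2 probes, which were averaged per array. Their r within an array was 0.364 to 0.849, median 0.702. Among called genes 0 to 3.85% per comparison had probes of opposite sign. Of 9858 probes 9632 had 1 gene symbol and 226 did not, 44 of these having several; all were tested and only features with 1 symbol were named. Of 4929 features, 4921 with a value on at least 2 arrays of every group were tested. Gene names are those of the platform annotation.

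The series text calls the repeats biological. Arrays of a group were compared through the difference of their log2 ratios. In 9 of 65 pairs this difference did not repeat between the 2 probes of a gene (r -0.00233 to 0.0317, against 0.113 to 0.488 in the 56 other pairs). These were all 5 rad3 sep1 pairs, replicates 1 and 3 of wild type at 30 min and of rad3 at 60 min, and replicates 2 and 3 of wild type and of chk1 at 60 min. The difference had an SD of 0.00621 to 0.0214 in the rad3 sep1 pairs, 0.0739 to 0.160 in the other 4 and 0.225 to 0.428 in the pairs kept apart. The rad3 sep1 arrays of a pair also differed by a shift of the whole array, with medians of -0.07 to 0.16, and the mean of both was used. Each of the 9 pairs was averaged into 1 sample, which gave 61 samples. The plan had named all 70 arrays as samples, so this departs from it, and the fit with 70 is kept as an alternative.

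Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over 25 groups of strain and time. The moderated test of limma was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The early response was the mean of 10 and 30 min minus 0 min and the late response the mean of 60 and 120 min minus 0 min, each time weighted equally. Differences between strains in the late response were interaction terms of the same fit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

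Lists of genes were written before the data were examined, as were the comparisons, the naming rule and the alternatives not marked as later. There were 19, of which 1 is not reported here. The others were G1/S (MBF), histone, mitosis and cytokinesis (forkhead), core environmental stress, oxidative stress (Pap1), chaperone, iron uptake (Fep1), iron-sulfur and heme protein, DNA replication factor, DNA repair, checkpoint, ribosomal protein, ribosome biogenesis, meiosis and mating, M-cell type, P-cell type, nitrogen starvation and auxotrophy marker genes. They were drawn up from general knowledge of the organism and some share members. The genes yox1, bir1 and hba2 were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over 380 tests of 19 lists in 20 comparisons; 139 passed, and 86 of these also with the correlation estimated per list. Members past the threshold were also counted with p adjusted over the list alone. Histone, ribosomal protein and mating-type genes include near-identical copies, so values of single members are uncertain.

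Named genes followed a rule. The first were rad3, cds1, chk1 and sep1 in every strain. Next came, per comparison, the 10 largest increases and 10 largest decreases past the threshold whose treated (or mutant) samples all lay on the same side of the mean of the 0 min (or comparison) samples; for differences between strains, the 10 largest each way past the threshold. Last came up to 4 members of each reported list with the smallest adjusted p among those that passed, or up to 2 where none passed. Where room was short, names were taken from the top. The genes of the comparison across strains repeat these.

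Replicate numbers were checked for pairing before fits were compared. Deviations of samples with the same number from their group means had r over 0.1 in 53 of 57 pairs (-0.073 to 0.639, median 0.399). Every pair was over 0.1 within cds1, within chk1, within wild type up to 30 min, and between untreated wild type and untreated cds1 or chk1, so the fit with the number as a block is given beside those results where it moves a count or call.

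Alternatives were: arrays centred on their median; quantile normalization between arrays; only genes with values on all 70 arrays; no filter; every probe as its own feature; only the strains of the comparison in the fit; robust eBayes; array weights; the replicate number as a fixed or random block; a change of at least 1.5-fold; each sample left out in turn; treated wild type against the reference channel alone; camera with an estimated correlation; and fry. Added after the data were seen were all 70 arrays as samples, either probe alone, chk1 as the comparison strain, mutants compared at later times, and all 56 or 84 splits of a strain into treated and 0 min samples with both treated times as 1 group. Random exchanges of sample labels, 100 per comparison or all 10 for 3 samples against 3, were run over 4919 genes.

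In a self-test, changes of 1.3, 1.5 and 2-fold were put into simulated arrays of the same design. The rates below hold for the simulated noise only. For the late response of wild type 34.3, 79.1 and 98.5% of changed genes were recovered, for that of rad3 sep1 7.46, 32.8 and 83.3%, for untreated rad3 40.3, 74.6 and 97.0%, and for the late difference of cds1 22.4, 56.7 and 93.9%. Unchanged genes made up 8.44, 4.65, 2.08 and 4.96% of the calls.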

Results

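Transcript levels of fission yeast (Schizosaccharomyces pombe) were measured on 70 2-colour arrays. Asynchronous cultures of 5 strains were treated with 8 mM hydroxyurea (HU), an inhibitor of ribonucleotide reductase that stalls DNA replication, for 0, 10, 30, 60 or 120 min. The strains were wild type, single mutants of rad3, cds1 and chk1, and a rad3 sep1 double mutant. Rad3 is the apical kinase of the DNA structure checkpoints, Cds1 is the effector kinase activated by stalled replication, Chk1 is the effector kinase of the DNA damage checkpoint, and Sep1 is a forkhead transcription factor of the cell cycle. Each value was the log2 ratio of the sample to an untreated wild-type reference. There were 15 arrays for wild type and each single mutant, 3 per time, and 10 for rad3 sep1. Of the array pairs within groups, 9 differed, apart from a shift of the whole array, by no more than noise between probes and were counted as 1 sample each. This left 61 samples in 25 groups: 13 of wild type, 14 of rad3, 15 of cds1, 14 of chk1 and 5 of rad3 sep1. Every rad3 sep1 group was then a single sample, which was assumed to vary like the samples of the other groups. The table held 9858 probe rows, 2 per gene feature, with 9727 to 9854 values per array and 0.238% of values missing. The number of arrays limits the precision.

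The deleted genes were compared across strains first, to see whether labels and ratios matched. The rad3 transcript had a mean log2 ratio of -2.20 ± 0.57 (SD, n = 14 samples) in rad3 and -2.36 ± 0.03 (n = 5) in rad3 sep1, against -0.18 ± 0.13 (n = 13) in wild type. It was -0.28 in cds1 and -0.21 in chk1. The cds1 transcript was at -2.45 ± 0.33 (n = 15) in cds1, 0.29 ± 0.19 in wild type, 0.40 in rad3, 0.28 in chk1 and -0.02 in rad3 sep1. The chk1 transcript was at -1.37 ± 0.23 (n = 14) in chk1 and -0.53 ± 0.18 in wild type, with -0.57 in rad3, -0.46 in cds1 and -0.67 in rad3 sep1. The sep1 transcript was at -3.54 ± 0.18 (n = 5) in rad3 sep1 and -0.09 ± 0.20 in wild type, with -0.12 in rad3, -0.18 in cds1 and -0.11 in chk1. Each of the 4 genes was thus lower in the strains named after it than in the others. During late HU treatment sep1 rose by 0.38 ± 0.10 in wild type, 0.45 ± 0.10 in cds1 and 0.43 ± 0.10 in chk1 ( ± SE of the limma fit). On the second probe alone the cds1 value was 0.25 and missed the threshold.

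The early response of wild type (mean of 10 and 30 min against 0 min, 5 samples against 3) asks which transcripts move within 30 min of treatment. The largest increases were in urg2 and urg1, genes induced by uracil. They rose by 2.22 ± 0.17 and 1.72 ± 0.17 (log2 ± SE). The small heat shock protein gene hsp16 rose by 1.66 ± 0.13 and the disaggregase gene hsp104 by 1.18 ± 0.20. The siderophore transporter gene str3 rose by 1.05 ± 0.14, and the ferric reductase gene frp1 by 0.93 ± 0.18. SPOM_SPAC521.03 and hsp9 each rose by 0.76. Transcripts of the G1/S transcription factor MBF rose too: cdt2, a ubiquitin ligase adaptor, by 0.94 ± 0.09, the replication licensing gene cdc18 by 0.78 ± 0.12, and the ribonucleotide reductase gene cdc22 and the cyclin gene cig2 by 0.58 each. Also higher were ish1 by 0.55, the sulfiredoxin gene srx1 by 0.55, the co-chaperone gene psi1 by 0.57, the iron permease gene fip1 by 0.70 and the ammonium transporter gene amt1 by 0.44. The 5 lower genes were ebp2 at -0.65 ± 0.16, rrp16 at -0.63 ± 0.15, acl4 at -0.52 ± 0.13, dbp2 at -0.49 ± 0.11, and SPOM_SPCC24B10.18 at -0.52. With limma, 33 genes were higher and 5 lower of 4921 tested. Of these, 5 were at least 2-fold higher. With the replicate number as a block, which these samples showed, the counts were 71 and 30. With quantile normalization between arrays the split was 42 higher and 25 lower, cdc22 and dbp2 missed the threshold at 0.48 and -0.47, and psi1 was at -0.53. On a single probe the calls of hsp104, frp1, ish1, srx1, psi1, cig2, fip1, amt1 and all 5 lower genes were lost, and with every probe as its own feature those of cig2, amt1 and the 5 lower genes. With only wild type in the fit those of frp1, srx1 and fip1 were lost. The count was 21 without replicate 3 of untreated wild type, and cig2 then missed the threshold at 0.51, amt1 at 0.37 and psi1 at 0.52. Of the 8 fits that each left out 1 sample, 6 ended the call of ebp2, 4 of rrp16, 7 of acl4, 5 of dbp2, 4 of SPOM_SPCC24B10.18 and 6 of fip1. Further, frp1 missed it at 0.76 without replicate 2 at 30 min. For srx1 this happened without replicate 2 at 0 min (0.45) and without the merged 30 min sample (0.47), and for psi1 without replicate 1 at 0 min (0.54) and the merged 30 min sample (0.52).

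Among fixed lists in early wild type, core environmental stress genes had a median log2 change of 0.38 (adjusted p = 2.23e-20). Of the 17 members 7 rose, or 9 adjusted over the list alone. MBF genes had a median of 0.10 and a mean of 0.24 (adjusted p = 3.70e-08), with 4 of 18 members higher, or 5 adjusted over the list alone. Iron uptake genes, repressed by Fep1 in iron-rich cells, had a median of 0.39 (adjusted p = 4.61e-10), and 3 of 11 rose, or 6 adjusted over the list alone. Nitrogen starvation genes had a median of 0.35 (adjusted p = 9.27e-07), with 2 of 7 higher, or 4 over the list alone. Chaperone genes had a median of 0.19 (adjusted p = 4.77e-09), with 3 of 14 higher, which quantile normalization took to 0.04 and past the threshold no more. Targets of the oxidative stress factor Pap1 had a median of 0.13 (adjusted p = 0.00158). Their call was lost with quantile normalization, with the first probe alone, and with an estimated correlation (adjusted p = 0.094). Ribosome biogenesis genes had a median of -0.14 (adjusted p = 0.00067). Histone genes, whose near-identical copies the probes may not tell apart, had a median of -0.10 (adjusted p = 0.0490, or adjusted p = 0.46 with an estimated correlation). That call was also lost with centred arrays, in the fry test, on either probe alone and in 5 of the 8 fits without a sample.

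The late response of wild type (60 and 120 min against 0 min, 5 samples against 3) asks which transcripts move with longer treatment. The largest increase was in hsp16, at 3.62 ± 0.13. The iron genes frp1 and str3 rose by 2.05 ± 0.18 and 1.89 ± 0.14, and urg2 rose by 1.91 ± 0.17. The MBF targets cdt2, cdc18, cig2 and cdc22 rose by 1.96 ± 0.09, 1.94 ± 0.12, 1.70 ± 0.11 and 1.57 ± 0.10. SPOM_SPAC27D7.09C rose by 2.04 ± 0.17 and hsp104 by 1.70 ± 0.20. The largest decreases included uds1, which peaks at septation, at -1.24 ± 0.10, the septum glucanase gene eng1 at -1.21 ± 0.12, SPOM_SPCC306.11 at -1.15 ± 0.11 and adg3 at -0.92 ± 0.15. Also lower were the RNA polymerase I subunit gene rpa34 at -1.14 ± 0.21, mpp6 at -0.93 ± 0.19 and rlp7 at -0.93 ± 0.13. SPOM_SPBC215.06C and ted1 were each at -1.15, and SPOM_SPBC31F10.17C at -0.97. The anaphase activator gene slp1 was at -0.90 ± 0.10 and the kinesin gene klp5 at -0.57 ± 0.12. The stress genes gst2, ish1 and tps1 rose by 1.33 ± 0.10, 1.16 ± 0.10 and 1.21 ± 0.11. In all, 604 genes were higher and 597 lower, 45 and 7 of them at least 2-fold. These named genes stayed past the threshold in each fit that left out 1 sample, while the count was 730 without replicate 2 of untreated wild type. At single times against 0 min, 14 genes differed at 10 min, 48 at 30 min, 478 at 60 min and 1235 at 120 min.

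**Figure D1:**
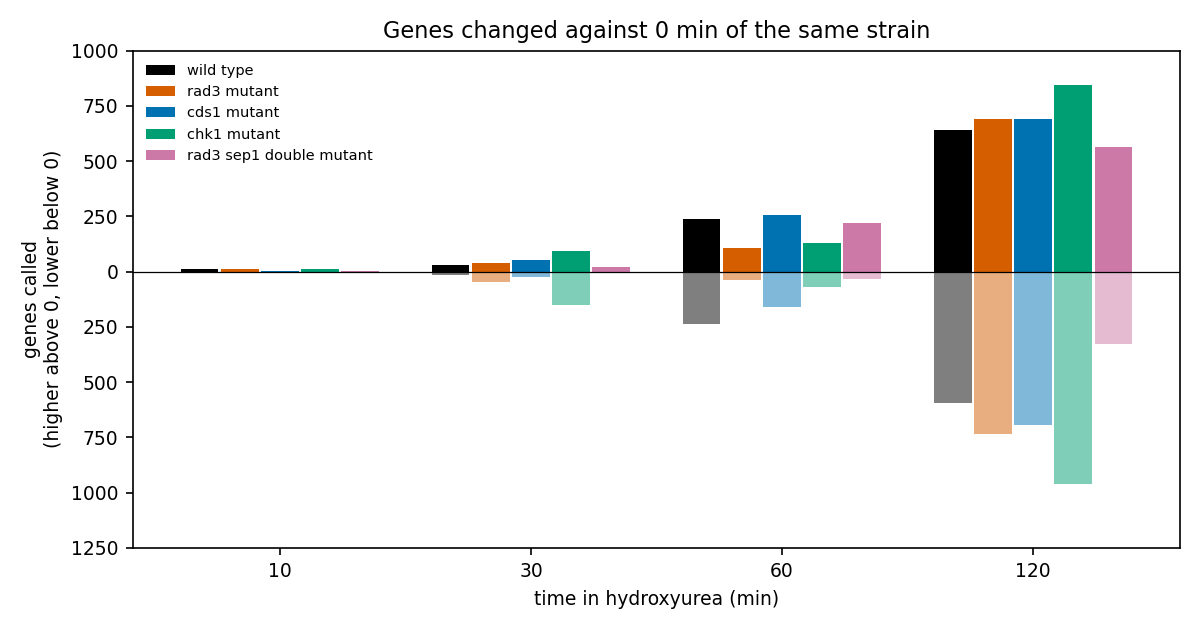
Number of genes past an adjusted p of 0.05 in limma (y axis; genes higher than at 0 min above 0, genes lower below 0) at 10, 30, 60 and 120 min of HU (x axis) in each of the 5 strains. In wild type 14 genes differed at 10 min and 1235 at 120 min.

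Of the lists in late wild type, MBF genes had a median log2 change of 0.46 (adjusted p = 1.93e-13), with 13 of 18 higher over all genes and adjusted over the list alone. Iron uptake genes had a median of 0.62 (adjusted p = 1.47e-08), with 8 of 11 higher, or 10 adjusted over the list alone. The sib2 gene of siderophore synthesis rose by 0.82 ± 0.15 and fip1 by 1.2 ± 0.17. Stress genes had a median of 1.01 (adjusted p = 1.85e-20), with 14 of 17 higher. Pap1 targets and chaperone genes each had a median of 0.32 (adjusted p = 1.47e-05 and 4.64e-07), with 9 of 14 and 7 of 14 higher. Over the lists alone 11 Pap1 targets rose and 1 fell, and 8 chaperone genes rose. With quantile normalization both lists missed the threshold, and psi1, which rose by 1.16 ± 0.12, was at -0.61. Histone genes had a median of 0.53 (adjusted p = 0.000105), with 7 of 10 higher, among them htb1 by 0.74 ± 0.11 and hta2 by 0.70 ± 0.11. Their call was lost with an estimated correlation (adjusted p = 0.094). Genes of mitosis and cytokinesis under forkhead factors had a median of -0.29 (adjusted p = 0.00279), with 2 higher and 10 lower of 18. For them adjusted p = 0.119 with an estimated correlation. The median of ribosome biogenesis genes was -0.30 (adjusted p = 0.00021) with 11 of 18 lower, among them ebp2 at -0.81 ± 0.16. Nitrogen starvation genes had a median of 0.33 (adjusted p = 0.00551), with 4 of 7 higher, but adjusted p = 0.0716 with an estimated correlation. The other lists given here missed the threshold. Their medians were -0.18 for iron-sulfur and heme protein genes, with glt1 at -0.63 ± 0.12 and pcl1 at -0.58 ± 0.12, -0.11 for 30 DNA replication factor genes, and -0.18 for 16 DNA repair genes. In the last list rad54 rose by 0.65 ± 0.10 and rad50 was at -0.47 ± 0.10. Checkpoint genes had a median of -0.08, with rad1 at -0.48 ± 0.11, and 117 ribosomal protein genes a median of -0.04. Meiosis and mating genes had a median of 0.15, with ste6 higher by 1.01 ± 0.28, and auxotrophy marker genes 0.17, with his3 higher by 0.41 ± 0.10. Calls of rad54, ste6 and his3 were lost on a single probe. M-cell type genes had a median of -0.19, and 3 P-cell type genes had a mean of 0.06 with a median just below 0 (adjusted p = 0.807). Against the reference channel, without subtracting 0 min, the ribosomal protein median was 0.42.

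**Figure D2:**
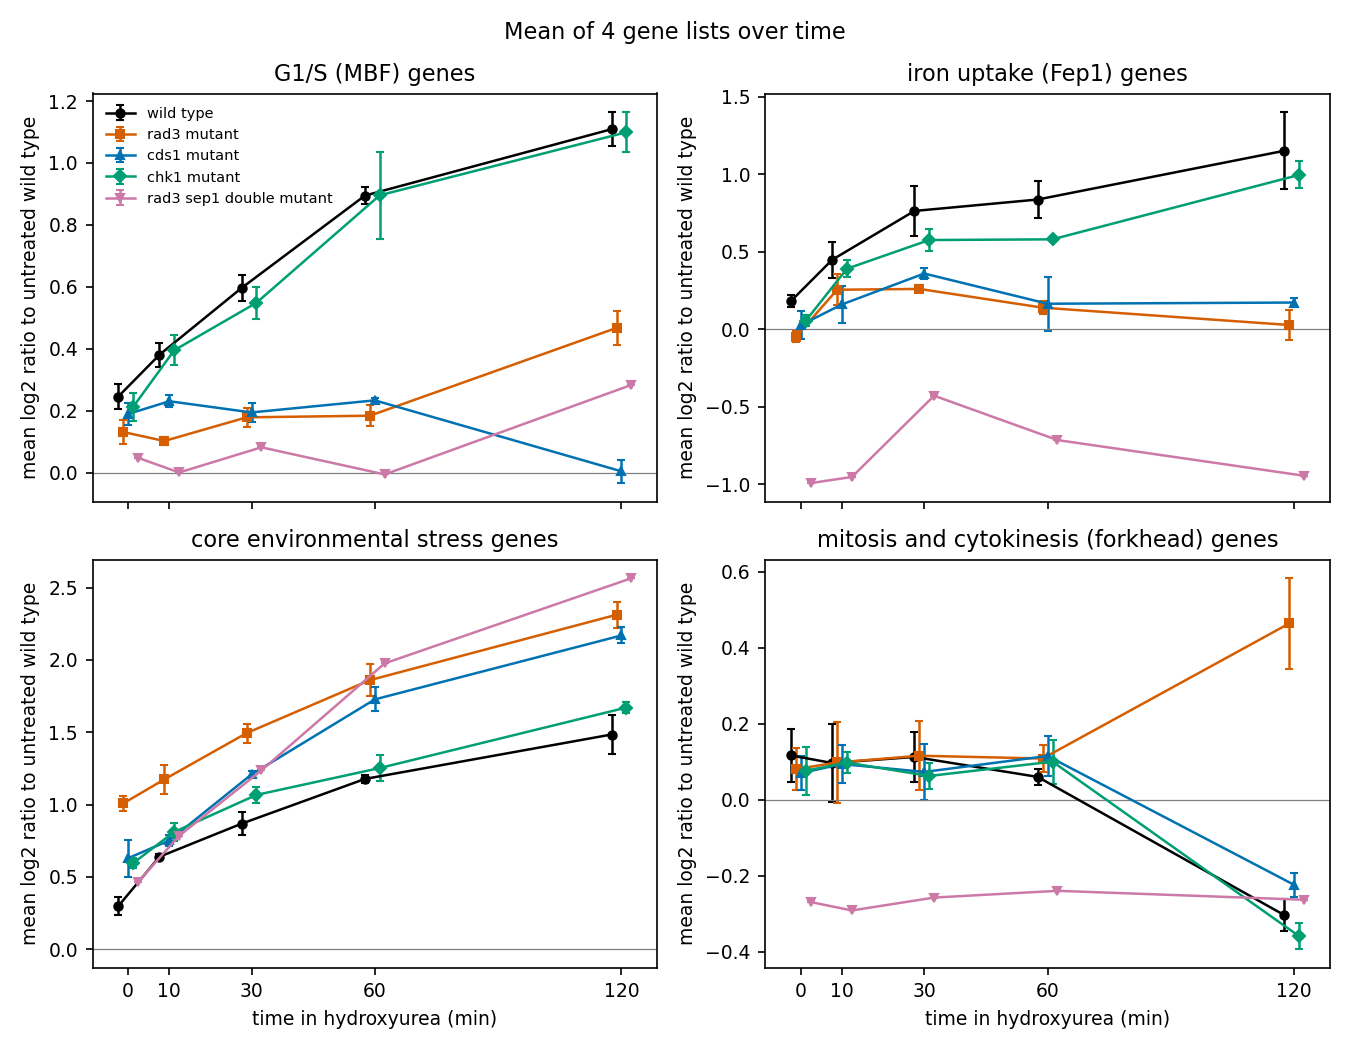
Mean log2 ratio to untreated wild type (y axis) of the MBF, iron uptake, core stress and forkhead lists against minutes in HU (x axis), with 1 line per strain. Error bars are the SD between samples, and rad3 sep1, with a single sample per time, has none; the wild-type MBF mean went from 0.25 at 0 min to 1.11 at 120 min.

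The rad3 mutant was compared with itself at 0 min, to see which HU responses occur without the apical checkpoint kinase. Early on (6 samples against 3), urg2 and urg1 rose by 2.41 ± 0.16 and 1.97 ± 0.17 and SPOM_SPAC521.03 by 0.99 ± 0.08. The sulfate transporter gene sul2 rose by 0.72 ± 0.10, the proline permease gene put4 by 0.69 ± 0.11, srx1 by 0.68 ± 0.12 and amt1 by 0.64 ± 0.09. The largest decreases were in rrp1402 at -0.91 ± 0.20, SPOM_SPAC1B9.03C at -0.87 ± 0.16, rrp36 at -0.76 ± 0.14, rpa34 at -0.76 ± 0.21, acl4 at -0.76 ± 0.13 and spb4 at -0.70 ± 0.13. Here 41 genes were higher and 69 lower. All 9 fits that left out 1 sample moved this count by over 1.5 times. It was 51, 38 and 24 without replicate 1, 2 or 3 at 0 min, 67, 29 and 198 without replicate 1, 2 or 3 at 10 min, and 193, 38 and 50 without replicate 1, 2 or 3 at 30 min. Without replicate 3 at 0 min rrp1402 missed the threshold at -0.85, and rpa34 missed it in 7 of the 9 fits. On a single probe the calls of srx1, amt1, rrp36 and rpa34 were lost. For ribosome biogenesis genes the median was -0.21 (adjusted p = 3.81e-05), iron uptake genes 0.34 (adjusted p = 3.05e-05) and nitrogen starvation genes 0.43 (adjusted p = 2.87e-08). The median of stress genes was 0.33 (adjusted p = 2.41e-10) and Pap1 targets 0.15 (adjusted p = 0.000911). Both were past the threshold no more with quantile normalization, and Pap1 targets had adjusted p = 0.0757 with an estimated correlation. M-cell type genes had a median of 0.22 (adjusted p = 0.0307, or adjusted p = 0.29 with an estimated correlation). They missed the threshold with quantile normalization, with array weights, in the fry test, without replicate 3 at 0 min (0.09) and without replicate 3 at 30 min (0.21). The median of MBF genes was 0.06 (adjusted p = 0.807).

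Late in rad3 (5 samples against 3), hsp16 rose by 2.23 ± 0.13, urg2 by 1.87 ± 0.17 and the glutathione transferase gene gst2 by 1.75 ± 0.10. The alcohol dehydrogenase gene adh8 rose by 1.63 ± 0.17, the glyoxalase gene hsp3101 by 1.53 ± 0.15, SPOM_SPAC2F3.05C by 1.45 ± 0.10, the metallothionein gene zym1 by 1.42 ± 0.20, urg1 by 1.42 ± 0.17 and srx1 by 1.41 ± 0.12. With quantile normalization hsp16 and zym1 missed the threshold, hsp104 was at -0.10 (1.21 ± 0.20 before), and psi1 at -0.20 (0.82 ± 0.12 before). The largest decreases were in the helicase gene dbp2 at -1.05 ± 0.11, rrp36 at -0.94 ± 0.15, the flocculin gene pfl3 at -0.94 ± 0.11, SPOM_SPBC365.04C at -0.91 ± 0.16, SPOM_SPBC215.06C at -0.90 ± 0.22 and the sulfite reductase gene met10 at -0.89 ± 0.09. There were 512 genes higher and 440 lower, 41 and 1 of them at least 2-fold, and 592 in all without replicate 3 at 0 min. All 17 stress genes rose, with a median of 1.12 (adjusted p = 1.09e-28), and 10 of 14 Pap1 targets rose, with a median of 0.46 (adjusted p = 2.26e-09). The median of chaperone genes was 0.39 (adjusted p = 1.94e-07), but -0.02 with quantile normalization. Ribosome biogenesis genes had a median of -0.44 (adjusted p = 4.67e-07), with 13 of 18 lower. Ribosomal protein genes had a median of -0.23 (adjusted p = 1.38e-07), or adjusted p = 0.582 with an estimated correlation, and missed the threshold in the fry test. For MBF genes the median was 0.30 (adjusted p = 0.0164), with 8 higher and 1 lower, or 10 and 1 adjusted over the list alone. Their call was lost with quantile normalization (0.10) and with an estimated correlation (adjusted p = 0.0742). Here cdc18 rose by 0.49 ± 0.12 and cdt2 by 0.37 ± 0.09, while cdc18 missed the threshold with quantile normalization at 0.27, and each missed it on a single probe. Forkhead genes had a median of 0.22 (adjusted p = 0.0232, or adjusted p = 0.266 with an estimated correlation), and spo12 rose by 0.77 ± 0.12. Histone genes had a median of 0.26 (adjusted p = 0.0192, or adjusted p = 0.357 with an estimated correlation). Quantile normalization ended the calls of forkhead and histone genes. The forkhead call was also lost without replicate 1 at 0 min (0.21) and replicate 2 at 120 min (0.19). The histone call was lost without replicate 1 at 0 min (0.22), replicate 2 at 0 min (0.21) and replicate 3 at 120 min (0.23).

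The cds1 mutant was compared with itself at 0 min, to see which responses occur without the replication checkpoint effector. Early on (6 samples against 3), urg2 and urg1 rose by 2.68 ± 0.16 and 2.30 ± 0.17, hsp16 by 1.06 ± 0.13 and SPOM_SPAC521.03 by 0.95 ± 0.08. SPOM_SPBPB10D8.02C rose by 0.65 ± 0.12, srx1 by 0.64 ± 0.12, hsp9 by 0.62 ± 0.12, SPOM_SPAC2F3.05C by 0.60 ± 0.09 and sul2 by 0.56 ± 0.10. The largest decreases were in ppp1 at -0.56 ± 0.10 and spb4 at -0.53 ± 0.13, which act in ribosome production. Of 4921 genes 20 were higher and 6 lower. With the replicate number as a block, which the samples of this strain showed, the counts were 79 and 44. Without replicate 1 or 2 at 0 min the count was 17 or 13. Without replicate 2 at 0 min hsp9 missed the threshold at 0.56. The call of spb4 was lost in 7 of the 9 fits without a sample, and those of hsp16 and hsp9 with quantile normalization. Calls of SPOM_SPBPB10D8.02C, srx1, SPOM_SPAC2F3.05C, sul2, ppp1 and spb4 were lost on a single probe, and of sul2 and spb4 with only cds1 in the fit. The median of ribosome biogenesis genes was -0.22 (adjusted p = 8.75e-07) with no member past the threshold, or 4 lower adjusted over the list alone. For stress genes the median was 0.24 (adjusted p = 4.47e-16), with 5 of 17 higher, or 8 over the list alone, and iron uptake genes 0.27 (adjusted p = 9.40e-05). For chaperone genes the median was 0.03 and a mean of 0.16 (adjusted p = 0.0105, or adjusted p = 0.187 with an estimated correlation), with a median of -0.08 after quantile normalization. Pap1 targets had a median of 0.08 (adjusted p = 0.00164, or adjusted p = 0.094 with an estimated correlation), and missed the threshold after quantile normalization. Ribosomal protein genes had a median of -0.08 (adjusted p = 0.00274, or adjusted p = 0.751 with an estimated correlation). That call was lost in the fry test, without replicate 2 at 10 min (-0.04) and without replicate 2 at 30 min (-0.04). Nitrogen starvation genes had a median of 0.23 (adjusted p = 6.30e-05).

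Late in cds1 (6 samples against 3), hsp16 rose by 3.32 ± 0.13, gst2 by 2.08 ± 0.09 and urg2 by 2.08 ± 0.16. Then came hsp3101 with 2.00 ± 0.15, zym1 with 1.97 ± 0.19, SPOM_SPCC338.18 with 1.88 ± 0.23, hsp104 with 1.86 ± 0.19 and SPOM_SPCC663.08C with 1.84 ± 0.13. Quantile normalization ended the calls of hsp16 and hsp104. The decreases were led by pfl3 at -1.2 ± 0.11 and sap1, which encodes a replication fork barrier protein, at -1.2 ± 0.14. The glutathione transporter gene pgt1 was at -0.93 ± 0.12, the amino acid transporter gene aat1 at -0.92 ± 0.11, the non-coding nc-pho1 at -0.91 ± 0.11, the nucleolar protein gene gar2 at -0.90 ± 0.12, met10 at -0.87 ± 0.09 and uds1 at -0.85 ± 0.10. There were 610 genes higher and 618 lower, 61 and 2 of them at least 2-fold, and 879 and 969 with the replicate block. MBF genes had a median of -0.07 (adjusted p = 0.574), with 1 higher and 2 lower, of which cig2 was at -0.41 ± 0.11 and, on the second probe alone, missed the threshold at -0.33. Stress genes had a median of 1.42 (adjusted p = 1.01e-29), with 14 of 17 higher, or 15 over the list alone. Of 14 Pap1 targets 13 rose, with a median of 0.39 (adjusted p = 3.47e-11). The catalase gene ctt1 rose by 1.04 ± 0.11, but by 0.12 on the first probe alone, which missed the threshold. Chaperone genes had a median of 0.26 (adjusted p = 2.20e-07), but -0.03 with quantile normalization, when psi1 was at -0.38 and ssa1 at -0.22. For ribosome biogenesis genes the median was -0.43 (adjusted p = 2.18e-05). Ribosomal protein genes had a median of -0.32 with 1 higher and 41 lower (adjusted p = 1.84e-10, or adjusted p = 0.49 with an estimated correlation), and 1 higher and 50 lower adjusted over the list alone. Iron uptake genes had 0.06 (adjusted p = 0.357).

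The chk1 mutant was compared with itself at 0 min, to see which responses occur without the damage checkpoint effector. Early on (6 samples against 3), urg2 and urg1 rose by 2.07 ± 0.16 and 1.48 ± 0.17, hsp16 by 1.22 ± 0.13, cdt2 by 0.96 ± 0.09 and hsp104 by 0.89 ± 0.19. SPOM_SPAC521.03 rose by 0.81 ± 0.08, str3 by 0.78 ± 0.14, fip1 by 0.75 ± 0.16 and ams2, a GATA factor gene, by 0.74 ± 0.11. The decreases were in cgr1 at -0.66 ± 0.17, rrp16 at -0.56 ± 0.15, cnl2 at -0.53 ± 0.11 and the iron transporter gene pcl1 at -0.51 ± 0.12. There were 36 genes higher and 24 lower, 104 and 123 with quantile normalization, and 218 and 190 with the replicate block, which the samples of this strain showed. The count was 35 without replicate 2 at 0 min, 26 without replicate 3 at 0 min, 95 without replicate 3 at 10 min and 39 without replicate 2 at 30 min. Quantile normalization put hsp16, at 1.84 in untreated chk1, at -0.21. This setting limits the rise of genes already high at 0 min. Without replicate 1 at 0 min hsp104 missed the threshold at 0.82 and pcl1 at -0.43, without replicate 2 fip1 did at 0.61, and without replicate 3 cnl2 did at -0.49. The calls of cgr1 and rrp16 were lost in 6 and 7 of the 9 fits without a sample, and with only chk1 in the fit. On a single probe the calls of hsp104, str3, cgr1, rrp16, cnl2 and pcl1 were lost. The median of MBF genes was 0.17 (adjusted p = 1.32e-07), with 4 of 18 higher, or 7 over the list alone. The median of stress genes was 0.35 (adjusted p = 6.70e-11), iron uptake genes 0.40 (adjusted p = 8.30e-09), nitrogen starvation genes 0.34 (adjusted p = 3.43e-07) and ribosome biogenesis genes -0.17 (adjusted p = 0.000948). The median of chaperone genes was 0.15 (adjusted p = 6.71e-05), and -0.05 with quantile normalization. Pap1 targets had a median of 0.15 (adjusted p = 0.000331, or adjusted p = 0.0514 with an estimated correlation). Histone genes had a median of -0.15 (adjusted p = 0.01, or adjusted p = 0.293 with an estimated correlation). Their call was lost without replicate 1 at 0 min (-0.11), with array weights and in the fry test.

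Late in chk1 (5 samples against 3), hsp16 rose by 2.73 ± 0.13, cdt2 by 2.00 ± 0.09, SPOM_SPAC27D7.09C by 1.87 ± 0.17, frp1 by 1.82 ± 0.18, ams2 by 1.75 ± 0.12 and urg2 by 1.72 ± 0.17. Each of cdc22, cig2, cdc18 and nc-pho1 rose by 1.71. With quantile normalization hsp16 alone of these missed the threshold. The largest decreases were in uds1 at -1.29 ± 0.10, adg1 at -1.25 ± 0.14, mpp6 at -1.11 ± 0.19, the histone methyltransferase gene set7 at -1.05 ± 0.11, SPAC23A1.01c at -1.03 ± 0.10 and SPOM_SPBC215.06C at -1.03 ± 0.22. Also lower were rpa34 at -1.01 ± 0.21, rlp7 at -1.0 ± 0.13 and slp1 at -0.78 ± 0.10. There were 621 genes higher and 731 lower, 38 and 9 of them at least 2-fold. For MBF genes the median was 0.56 (adjusted p = 8.07e-15), with 12 of 18 higher, or 14 over the list alone. Histone genes had a median of 0.66 (adjusted p = 4.70e-06), with 8 of 10 higher. The median of iron uptake genes was 0.56 (adjusted p = 1.38e-07), with 9 of 11 higher, or 10 over the list alone. For stress genes the median was 0.91 (adjusted p = 2.52e-16) and Pap1 targets 0.33 (adjusted p = 2.53e-06). Nitrogen starvation genes had a median of 0.34 (adjusted p = 0.000149), with 6 of 7 higher, and ribosome biogenesis genes -0.32 (adjusted p = 0.000611). For chaperone genes the median was 0.30 (adjusted p = 5.33e-05), but -0.16 with quantile normalization, when psi1 was at -0.43. Forkhead genes had a median of -0.25 (adjusted p = 0.0210, or adjusted p = 0.259 with an estimated correlation), lost without replicate 2 at 0 min (-0.21) and with the first probe alone.

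The rad3 sep1 double mutant was compared with itself at 0 min, to see which responses occur without both the kinase and the forkhead factor. Early on (2 samples against 1), urg2 and urg1 rose by 2.39 ± 0.28 and 1.96 ± 0.29, srx1 by 1.17 ± 0.20 and SPOM_SPAC521.03 by 1.04 ± 0.15. The trehalose synthesis gene tps1 rose by 0.91 ± 0.18, SPOM_SPAC26F1.07 by 0.86 ± 0.16 and SPOM_SPBC30D10.14 by 0.83 ± 0.17, and these 3 missed the threshold with quantile normalization. Calls of all but urg2 were lost on a single probe. In limma 7 genes were higher and 0 lower, with 214 at an unadjusted p under 0.05. At 30 min the median log2 change of all genes was 0.11. Stress genes had a median of 0.63 (adjusted p = 6.33e-19), with 2 of 17 higher, or 12 over the list alone. Chaperone genes had a median of 0.43 (adjusted p = 1.03e-10), Pap1 targets 0.25 (adjusted p = 3.56e-08), nitrogen starvation genes 0.31 (adjusted p = 0.00158) and ribosome biogenesis genes -0.22 (adjusted p = 4.88e-07). Histone and iron uptake genes had medians of 0.31 and 0.33 (adjusted p = 0.00425 and 0.00502), but adjusted p = 0.258 and 0.142 with an estimated correlation, and neither passed in the fry test.

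Late in rad3 sep1 (2 samples against 1), hsp16 rose by 2.99 ± 0.22, gst2 by 2.96 ± 0.16, srx1 by 2.77 ± 0.20, SPOM_SPCC663.08C by 2.61 ± 0.23, urg2 by 2.59 ± 0.28, hsp104 by 2.40 ± 0.33, SPOM_SPAC750.01 by 2.36 ± 0.21 and adh8 by 2.31 ± 0.29. Of these hsp104 missed the threshold with quantile normalization. The decreases were led by dbp2 at -1.54 ± 0.18, gar2 at -1.48 ± 0.21, aat1 at -1.41 ± 0.19, the ribosomal protein gene rpl302 at -1.39 ± 0.26 and met10 at -1.38 ± 0.15, and rpl302 missed the threshold with quantile normalization at -0.91. There were 543 genes higher and 253 lower, 150 and 20 of them at least 2-fold, but 66 and 50 with quantile normalization. All 17 stress genes rose, with a median of 1.87 (adjusted p = 7.91e-31). Of 14 Pap1 targets 10 rose, or 11 over the list alone, with a median of 1.13 (adjusted p = 2.61e-15). The median of chaperone genes was 0.77 (adjusted p = 2.29e-10), with 9 of 14 higher, or 12 over the list alone. Ribosome biogenesis genes had a median of -0.74 (adjusted p = 1.84e-10), with 11 of 18 lower, or 12 over the list alone. Histone genes had a median of 0.55 (adjusted p = 0.0313) and nitrogen starvation genes 0.42 (adjusted p = 0.00935). Both calls were lost with quantile normalization and with an estimated correlation (adjusted p = 0.411 and adjusted p = 0.094). MBF genes had 0.14 (adjusted p = 0.853), with cdc22 higher by 0.48 ± 0.16, which missed the threshold with quantile normalization and on either probe.

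Untreated mutants were compared with untreated wild type to see how each mutant strain differs before HU (3 samples against 3). In rad3, hsp16 was higher by 2.69 ± 0.15, zym1 by 2.06 ± 0.22, SPOM_SPCC737.04 by 1.85 ± 0.21, SPOM_SPBC19C7.04C by 1.70 ± 0.17, lsd90 by 1.56 ± 0.15, SPOM_SPCC1739.08C by 1.46 ± 0.16 and hsp104 by 1.33 ± 0.22. Further, ddr48 was higher by 1.26 ± 0.13, hsp9 by 1.2 ± 0.14, the glyceraldehyde-3-phosphate dehydrogenase gene gpd3 by 1.17 ± 0.18, ish1 by 0.88 ± 0.11 and gst2 by 0.72 ± 0.11. The deleted rad3 was at -2.05 ± 0.27. On the second probe alone ddr48 missed the threshold at 0.07, and on the first SPOM_SPCC1739.08C at 0.16. There were 45 genes higher and 2 lower, and 29 in all without replicate 2 of untreated rad3. The median of stress genes was 0.49 (adjusted p = 8.01e-43), with 8 of 17 higher, or 10 over the list alone. Pap1 targets had a median of 0.20 (adjusted p = 1.01e-07). For chaperone genes the median was 0.11 (adjusted p = 1.12e-07), but -0.08 with quantile normalization. MBF genes had a median of -0.10 (adjusted p = 0.00174) and iron uptake genes -0.14 (adjusted p = 0.000163). M-cell type and nitrogen starvation genes had medians of -0.17 and 0.09 (adjusted p = 0.00906 and 0.0283, or adjusted p = 0.198 and 0.166 with an estimated correlation). The fry test passed neither of these 2. The M-cell call was lost without replicate 1 of wild type (-0.09) and replicate 3 of rad3 (-0.04). The nitrogen call was lost without replicate 2 of wild type (0.03) and replicates 1 or 3 of rad3 (0.11 and 0.11).

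In untreated cds1, hsp16 was higher by 1.64 ± 0.15 and SPOM_SPBPB10D8.04C by 0.64 ± 0.12. The deleted cds1 was at -2.49 ± 0.17, the uracil synthesis gene ura4 at -1.47 ± 0.13, SPOM_SPAC27D7.11C at -0.71 ± 0.15 and SPOM_SPBPJ4664.02 at -0.66 ± 0.14. These were the 2 genes higher and 4 lower. With the replicate number as a block, which these samples showed, there were 24 and 19, and with quantile normalization 28 and 16. The count was 3 without replicate 1 of cds1 and 14 without replicate 2 of cds1. SPOM_SPBPB10D8.04C missed the threshold without replicate 2 of wild type (0.60) or replicate 1 of cds1 (0.58), and SPOM_SPAC27D7.11C without replicate 1 of wild type (-0.58) or replicates 1 or 3 of cds1 (-0.69 and -0.69). The call of SPOM_SPBPJ4664.02 was lost in 4 of 6 such fits, all 3 on a single probe, and that of SPOM_SPAC27D7.11C with only these strains in the fit. For stress genes the median was 0.22 (adjusted p = 4.34e-11) and chaperone genes 0.20 (adjusted p = 2.08e-06). Pap1 targets (0.06), iron uptake genes (-0.11), ribosomal protein genes (0.11) and auxotrophy marker genes (-0.04) had adjusted p = 0.0348, 0.0312, 0.000227 and 0.0273. With an estimated correlation adjusted p = 0.29, 0.282, 0.694 and 0.269. Each of these 4 calls was lost in at least 1 of the 6 fits without a sample: ribosomal protein genes without replicate 2 of wild type (0.03), auxotrophy markers without replicate 1 of wild type (-0.03) or of cds1 (0.02). Pap1 targets were lost without replicate 2 of wild type (0.07) or replicates 2 or 3 of cds1 (0.10 and 0.10), and iron uptake genes without replicate 3 of wild type (-0.11) or replicates 2 or 3 of cds1 (-0.11 and -0.10).

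In untreated chk1, meu27 was higher by 1.75 ± 0.19, zym1 by 1.08 ± 0.22, hsp16 by 1.07 ± 0.15, SPOM_SPCC1739.08C by 0.71 ± 0.16 and ddr48 by 0.60 ± 0.13. The deleted chk1 was at -1.01 ± 0.15 and cbm1 at -0.76 ± 0.14. These were the 5 genes higher and 2 lower, with a count of 4 without replicate 2 of wild type and 3 without replicate 1 of chk1. In the last fit cbm1 missed the threshold at -0.63 and zym1 at 0.94. Also, zym1 missed it without replicate 2 or 3 of wild type (1.02 and 1.01). Of 6 fits without a sample, 5 ended the call of SPOM_SPCC1739.08C and 4 that of ddr48. On the second probe alone chk1 was at -0.66 and cbm1 at -0.44, both short of the threshold, and zym1, SPOM_SPCC1739.08C and ddr48 missed it on a single probe too. Stress genes had a median of 0.16 (adjusted p = 5.66e-11) and chaperone genes 0.13 (adjusted p = 2.26e-05), with 2 of 17 and 1 of 14 higher, or 5 and 4 over the lists alone. With the replicate block iron uptake genes passed as well, at -0.18.

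Untreated rad3 sep1 was compared with untreated wild type (1 sample against 3) and with untreated rad3, which shares its rad3 mutation, to see what loss of Sep1 changes. Against wild type, gdt1 was higher by 2.89 ± 0.53, SPOM_SPCC737.04 by 2.78 ± 0.29, SPOM_SPBPB2B2.18 by 2.63 ± 0.36, the hexose transporter gene ght5 by 2.24 ± 0.22, the biotin transporter gene vht1 by 1.95 ± 0.22 and hsp16 by 1.72 ± 0.21. SPOM_SPCC306.11 was at -4.13 ± 0.17, adg1 at -3.73 ± 0.23, sep1 at -3.44 ± 0.16, uds1 at -3.13 ± 0.16, eng1 at -3.13 ± 0.19, exg1 at -2.79 ± 0.17, cts2 at -2.69 ± 0.21, str3 at -2.48 ± 0.23, gal1 at -2.38 ± 0.24 and cdm1 at -2.37 ± 0.19. There were 273 genes higher and 659 lower, 24 and 88 of them at least 2-fold. The split was 409 to 501 with centred arrays and 516 to 519 with quantile normalization. Forkhead genes had a median of -0.41 (adjusted p = 0.00756), with 1 higher and 8 lower, or 1 and 9 over the list alone. For them adjusted p = 0.174 with an estimated correlation. For iron uptake genes the median was -1.43 (adjusted p = 4.15e-07), with 7 of 11 lower, among them fio1 at -2.12 ± 0.26 and frp1 at -2.31 ± 0.29. Iron-sulfur and heme protein genes had a median of 0.55 (adjusted p = 0.000428), with 5 of 10 higher, or 6 over the list alone, among them pcl1 by 0.99 ± 0.20. Ribosomal protein genes had a median of 0.12 (adjusted p = 0.00263, or adjusted p = 0.751 with an estimated correlation). Their call was lost with quantile normalization, in the fry test and without replicate 2 of wild type (0.04).

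Against untreated rad3 (1 sample against 3), ght5 was higher by 2.23 ± 0.22, vht1 by 2.13 ± 0.22, SPOM_SPBPB2B2.18 by 1.99 ± 0.36, gdt1 by 1.72 ± 0.53 and SPOM_SPBC25B2.08 by 1.59 ± 0.18. Without replicate 1 of rad3 gdt1 missed the threshold at 1.42, as it did with only these strains in the fit. SPOM_SPCC306.11 was at -4.04 ± 0.17, adg1 at -3.67 ± 0.23, sep1 at -3.44 ± 0.16, uds1 at -3.07 ± 0.16, exg1 at -3.00 ± 0.17, eng1 at -2.76 ± 0.19 and cts2 at -2.54 ± 0.21. There were 311 genes higher and 772 lower, 463 and 608 with centred arrays, and 519 and 533 with quantile normalization. Forkhead genes had a median of -0.47 (adjusted p = 0.0232, or adjusted p = 0.266 with an estimated correlation), with 1 higher and 9 lower, including slp1 at -0.95 ± 0.16, myp2 at -1.15 ± 0.20 and spo12 at -0.87 ± 0.19. On a single probe slp1 and spo12 missed the threshold. The cyclin gene cig2 was higher by 1.00 ± 0.18. MBF genes had a median of -0.12 while their test pointed up (adjusted p = 0.94), with 3 higher and 3 lower, or 3 and 4 over the list alone. The median of stress genes was -0.75 (adjusted p = 0.00057, or adjusted p = 0.0699 with an estimated correlation), with 9 of 17 lower, including hsp9 at -1.67 ± 0.19 and gpx1 at -1.26 ± 0.20. Iron uptake genes had a median of -0.93 (adjusted p = 9.57e-05), and iron-sulfur and heme protein genes 0.40 (adjusted p = 0.00263). Ribosomal protein genes had a median of 0.11 (adjusted p = 0.00074, or adjusted p = 0.713 with an estimated correlation), with 11 higher and 1 lower, or 9 and 0 over the list alone. The gene rps001 was higher by 1.22 ± 0.19.

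The late response of rad3 minus that of wild type asks which late changes differ without the apical kinase. For uds1 the difference was 1.71 ± 0.14, the largest, for SPOM_SPCC306.11 it was 1.71 ± 0.16, for exg1 1.50 ± 0.15, for eng1 1.49 ± 0.17 and for cts2 1.38 ± 0.19. It was 1.34 ± 0.15 for SPAC23A1.01c, 1.25 ± 0.15 for slp1, 1.23 ± 0.24 for adh8, 1.22 ± 0.17 for spo12 and 1.16 ± 0.14 for the wall glucanosyltransferase gene gas5. The largest negative ones were those of nc-pho1 with -2.03 ± 0.17, str3 -1.81 ± 0.20, frp1 -1.60 ± 0.26, cdt2 -1.59 ± 0.13, cdc18 -1.46 ± 0.17, hsp16 -1.38 ± 0.19, cig2 -1.37 ± 0.16, cdc22 -1.21 ± 0.14, ams2 -1.15 ± 0.17 and tos4 -1.07 ± 0.21. For hsp16, higher by 2.69 in untreated rad3, the level stayed above wild type at 60 and 120 min, by 1.22 and 1.38. Of the named genes adh8 and tos4 missed the threshold with quantile normalization. The difference passed for 34 genes upwards and 30 downwards. MBF genes had a median difference of -0.40 (adjusted p = 1.02e-15), with 6 of 18 lower, or 8 lower and 1 higher over the list alone. Forkhead genes had 0.42 (adjusted p = 3.25e-11), with 4 of 18 higher, or 9 over the list alone. Iron uptake genes had -0.53 (adjusted p = 1.84e-10), with 4 of 11 lower, or 7 over the list alone. Pap1 targets had a median of 0.13 (adjusted p = 0.0360), histone genes -0.22 (adjusted p = 0.0348), ribosomal protein genes -0.20 (adjusted p = 9.16e-06) and M-cell type genes 0.25 (adjusted p = 0.0250). All 4 were lost in the fry test and with an estimated correlation (adjusted p = 0.29, 0.424, 0.637 and 0.281). Leaving out 1 sample ended the call of Pap1 targets in 8, of histone genes in 6 and of M-cell type genes in 3 of 16 fits, those without replicate 1 of wild type at 0 min (0.28), replicate 3 of wild type at 120 min (0.22) or replicate 3 of rad3 at 0 min (0.16). With quantile normalization the Pap1, histone and ribosomal protein calls were lost, at -0.08, -0.06 and -0.06. For stress genes the median was 0.05, or -0.23 with quantile normalization.

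The late response of cds1 minus that of wild type asks the same of the replication effector. The largest positive differences were SPOM_SPCC663.08C with 1.42 ± 0.19, ted1 with 1.40 ± 0.39, adh8 with 1.33 ± 0.24, SPOM_SPCC338.18 with 1.32 ± 0.33, hsp3101 with 1.11 ± 0.21 and SPOM_SPCC18B5.02C with 1.04 ± 0.21. The call of ted1 was lost in 11 and that of SPOM_SPCC338.18 in 4 of the 17 fits without a sample, and quantile normalization ended 4 of these 6 calls, those of ted1, SPOM_SPCC338.18, hsp3101 and SPOM_SPCC18B5.02C. The largest negative ones were nc-pho1 with -2.39 ± 0.17, cig2 with -2.11 ± 0.16, cdc18 with -2.09 ± 0.17, str3 with -1.90 ± 0.20, cdt2 with -1.70 ± 0.13, tos4 with -1.64 ± 0.20, frp1 with -1.64 ± 0.26, cdc22 with -1.61 ± 0.14, the licensing gene cdt1 with -1.55 ± 0.25 and ams2 with -1.22 ± 0.16. The difference passed for 54 genes upwards and 52 downwards, or 20 and 29 with quantile normalization. The count was 55, 55 and 63 without replicate 1, 2 or 3 of wild type at 0 min, 58 without the merged wild-type sample at 60 min, and 62 and 68 without replicate 1 or 2 of cds1 at 0 min. The median of MBF genes was -0.52 (adjusted p = 5.72e-23), with 9 of 18 lower, or 14 over the list alone. Iron uptake genes had -0.47 (adjusted p = 6.67e-09), with 4 of 11 lower, among them fip1 with -1.03 ± 0.24. For stress genes the median was 0.19 (adjusted p = 9.57e-05), with 4 of 17 higher, or 8 over the list alone. With quantile normalization their median was 0.06 and the test pointed down. Pap1 targets had 0.19 (adjusted p = 0.000248), with 5 of 14 higher, among them gst2 with 0.76 ± 0.13 and ctt1 with 0.69 ± 0.15. On the first probe alone ctt1 had -0.09 and gst2 missed the threshold. With quantile normalization gst2, ctt1 and fip1 missed it. Histone genes had -0.35 (adjusted p = 0.000118), DNA repair genes 0.14 (adjusted p = 0.0178), ribosomal protein genes -0.28 (adjusted p = 1.10e-08) and nitrogen starvation genes -0.32 (adjusted p = 0.0180). With an estimated correlation these 4 had adjusted p = 0.0965, 0.29, 0.546 and 0.129. The last was also lost without replicate 2 of untreated wild type (-0.21).

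The late response of chk1 minus that of wild type had 0 genes past the threshold in limma, with 109 at an unadjusted p under 0.05. The smallest adjusted p among listed genes was for hsp16, with -0.88 ± 0.19 (adjusted p = 0.136). Among MBF genes cdc18 had -0.24 ± 0.17 and msh6 0.17 ± 0.14. Among checkpoint genes tel1 had 0.71 ± 0.22, and among iron uptake genes str3 had -0.50 ± 0.20. Stress and chaperone genes had medians of -0.12 and -0.13 (adjusted p = 0.00672 and 0.00731), lost with an estimated correlation (adjusted p = 0.17 and 0.164). M-cell type and nitrogen starvation genes had medians of 0.19 and 0.20 (adjusted p = 0.0220 and 0.0326), lost in the same way (adjusted p = 0.27 and 0.18). Without replicate 1 of chk1 at 60 min the stress call (-0.07) and the chaperone call (-0.03) were lost. Without replicate 2 or 3 of wild type at 0 min the stress call (-0.10) or the chaperone call (-0.12) was lost. The M-cell and nitrogen calls were lost in 6 and 8 of 16 such fits and with quantile normalization, and the fry test passed none of the 4 lists.

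The late response of rad3 sep1 minus that of wild type compares changes, not levels, without both genes. SPOM_SPCC663.08C had 2.20 ± 0.26, SPOM_SPAC750.01 1.96 ± 0.25, SPOM_SPCC306.11 (low untreated) 1.92 ± 0.22, adh8 1.92 ± 0.33, srx1 1.76 ± 0.23 and gst2 1.63 ± 0.19. The negative differences were led by str3 with -1.88 ± 0.28, cig2 with -1.84 ± 0.22, cdc18 with -1.73 ± 0.24, frp1 with -1.57 ± 0.36, cdt2 with -1.57 ± 0.18 and fip1 with -1.35 ± 0.33. With quantile normalization SPOM_SPCC663.08C, adh8, gst2, frp1 and fip1 missed the threshold. On a single probe str3, frp1 and fip1 did, and with only these strains frp1. The difference passed for 91 genes upwards and 29 downwards, or 20 and 24 with quantile normalization. For MBF genes the median was -0.50 (adjusted p = 2.52e-16), with 5 lower, or 9 over the list alone. Stress genes had 0.80 (adjusted p = 4.67e-15), with 9 higher, or 12 higher and 1 lower over the list alone. Pap1 targets had 0.84 (adjusted p = 5.21e-15), with 7 higher, or 11 over the list alone. Iron uptake genes had -0.57 (adjusted p = 5.58e-07) and ribosome biogenesis genes -0.36 (adjusted p = 3.65e-07). Forkhead and chaperone genes had 0.25 and 0.39 (adjusted p = 0.0286 and 0.0024), but adjusted p = 0.281 and 0.105 with an estimated correlation. Without replicate 2 of untreated wild type the forkhead call was lost (0.20), and quantile normalization ended the chaperone call. Histone genes had a median of 0.17 and a mean of -0.01 while their test pointed down (adjusted p = 0.602).

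The late response of rad3 sep1 minus that of rad3 compares changes, not levels, when sep1 is lost along with rad3. SPOM_SPAC977.14C had 1.64 ± 0.30, SPOM_SPAC750.01 1.43 ± 0.25, srx1 1.36 ± 0.23, SPOM_SPAC26H5.09C 1.29 ± 0.30, SPOM_SPCC663.08C 1.24 ± 0.26, the glutaredoxin gene grx1 1.23 ± 0.24, gst2 1.21 ± 0.19, nc-pho1 1.21 ± 0.23, tps3 1.2 ± 0.26 and the glucose-6-phosphate dehydrogenase gene zwf1 1.2 ± 0.29. Lower were mrpl20 with -1.04 ± 0.25 and SPOM_SPCC553.12C with -0.82 ± 0.20. The difference passed for 38 genes upwards and 2 downwards, or 5 and 1 with quantile normalization. Of the named genes only SPOM_SPAC977.14C, SPOM_SPAC750.01, srx1 and grx1 kept their calls there. Without replicate 3 of rad3 at 0 min SPOM_SPAC26H5.09C (1.21), zwf1 (1.05) and mrpl20 (-1.02) missed the threshold. Without the merged rad3 sample at 60 min zwf1 (1.17) and mrpl20 (-1.02) did, and without replicate 2 of rad3 at 0 min mrpl20 did (-0.97). SPOM_SPCC553.12C missed it in 4 of 8 such fits. With only these strains in the fit SPOM_SPAC26H5.09C, SPOM_SPCC663.08C, mrpl20 and SPOM_SPCC553.12C did. Stress genes had a median of 0.78 (adjusted p = 1.45e-16), with 6 of 17 higher, or 14 over the list alone. Pap1 targets had 0.58 (adjusted p = 4.15e-13), with 4 of 14 higher, or 11 over the list alone. Chaperone genes had 0.46 (adjusted p = 2.13e-06), with 6 of 14 higher over the list alone, and ribosome biogenesis genes -0.36 (adjusted p = 2.58e-06). Nitrogen starvation genes had 0.37 (adjusted p = 0.0029), forkhead genes -0.12 (adjusted p = 0.00257) and MBF genes -0.01 (adjusted p = 0.0425). These 3 were lost with an estimated correlation (adjusted p = 0.0508, 0.116 and 0.14). The MBF call was lost in 4 of 8 fits without a sample and with only these strains, the forkhead and nitrogen calls with quantile normalization, and the MBF and forkhead calls in the fry test. Of the named genes only SPOM_SPAC977.14C and gst2 kept their calls on either probe alone.

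**Figure D3:**
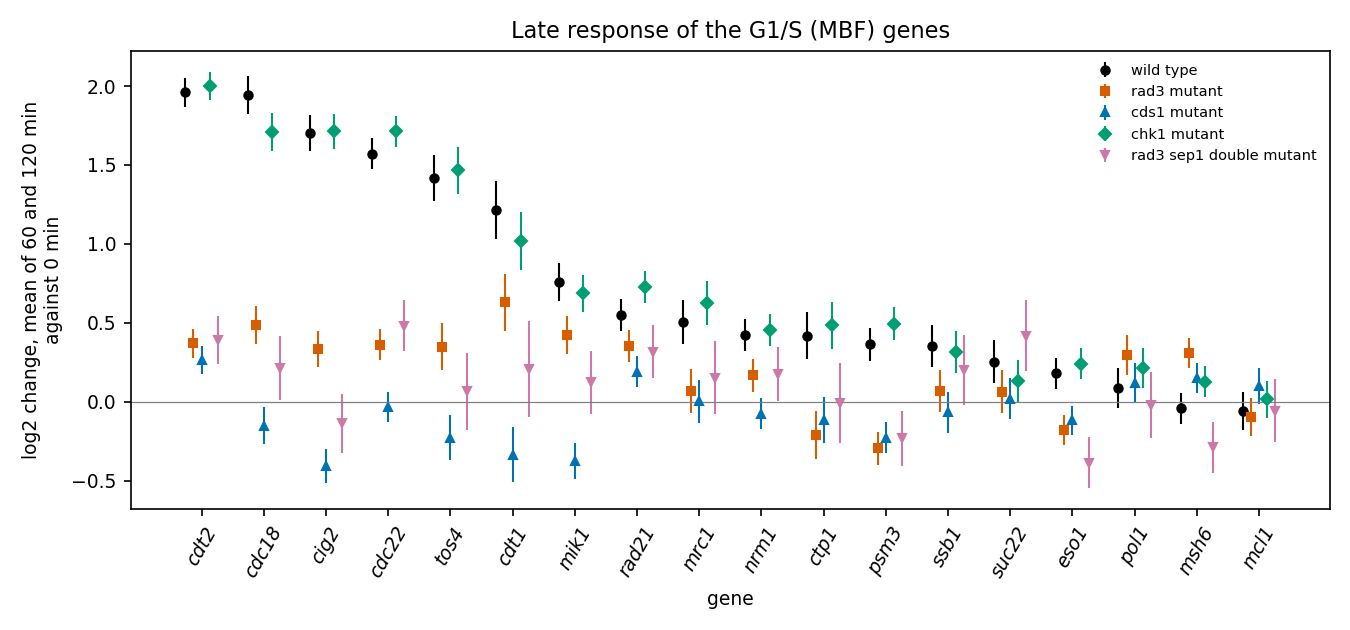
Late log2 change (mean of 60 and 120 min minus 0 min, y axis) of the 18 MBF genes (x axis) in the 5 strains, with the SE of the fit as bars. In wild type cdt2 rose by 1.96 and cdc18 by 1.94, and in chk1 by 2.00 and 1.71; in rad3 they rose by 0.37 and 0.49, and in cds1 cdc18 was not past the threshold.

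Late changes were then compared across strains, over genes, which are not independent replicates. The late log2 changes of wild type and chk1 had r = 0.882, those of rad3 and cds1 r = 0.827, those of wild type and rad3 r = 0.684, and those of wild type and cds1 r = 0.649. In wild type and rad3, 295 genes rose in both, 245 fell in both and 16 went opposite ways. In wild type and chk1, 419 rose in both, 466 fell in both and 0 went opposite ways in limma. In all 5 strains 184 genes rose late and 82 fell, and 4 rose early: urg1, urg2, srx1 and SPOM_SPAC521.03. With chk1 in place of wild type as the comparison strain, the late difference passed for 39 genes upwards and 33 downwards in rad3, and for 59 and 45 in cds1. For rad3 against chk1, cdt2 had -1.63 ± 0.13, cig2 -1.38 ± 0.16, uds1 1.77 ± 0.14, slp1 1.13 ± 0.15, and hsp16 -0.50 ± 0.19 (adjusted p = 0.259). For cds1 against rad3, 1 gene was higher and 17 lower. Here slp1 had -1.09 ± 0.14, uds1 -1.33 ± 0.14, eng1 -0.88 ± 0.17, cig2 -0.74 ± 0.16 and hsp16 1.09 ± 0.19.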

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

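The tests against chk1, at later times and with treated times as 1 group were chosen only after the results were seen; the others were planned. The next paragraph gives late responses that differed between strains in an interaction test; a list of those reported is given where it passed with both the preset and the estimated correlation. Values are median differences (log2).

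Against wild type, rad3 differed in 64 genes, with -0.40 for MBF, 0.42 for forkhead and -0.53 for iron uptake genes. The cds1 mutant differed in 106 genes, with -0.52 for MBF, 0.19 for stress, 0.19 for Pap1 and -0.47 for iron uptake genes. With quantile normalization its count was 49 and the stress test turned (median 0.06, past the threshold no more). The double mutant rad3 sep1 differed in 120 genes, with -0.50 for MBF, 0.80 for stress, 0.84 for Pap1, -0.57 for iron uptake and -0.36 for ribosome biogenesis genes. Against rad3 it differed in 40 genes, with 0.78 for stress, 0.58 for Pap1, 0.46 for chaperone and -0.36 for ribosome biogenesis genes. With quantile normalization its counts against wild type and rad3 were 44 and 6. All rad3 sep1 differences are changes from 1 untreated sample. Stress genes in it were at -0.75 against untreated rad3, and at 0.13 and 0.21 at 60 and 120 min, short of the threshold (adjusted p = 0.319 and 0.0709). Their late difference from rad3 thus largely follows the untreated one. Pap1 genes passed at both times, with 0.52 and 0.66.

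G1/S genes rose less in rad3 than in wild type, and in cds1 they did not rise as a list. Wild-type samples that stand apart were argued against by the difference with chk1 in their place, at most -0.40. Normalization between arrays was argued against by centred and quantile normalized arrays, at most -0.28, and a single deciding sample by leaving out each in turn, at most -0.35. A candidate explanation is that the late rise of MBF genes in HU depends on Rad3 and Cds1; it was found and tested on the same data. A different share of cells in S phase between strains stays open, since cell cycle position was not measured here.

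With strain labels exchanged, the late difference of cds1 from wild type (106 genes) had 59 as highest other. For rad3 it was 405 (real 64, 5 of 100 as large), for chk1 10 (real 0, 100 of 100). The exchanges with 405 and 357 genes kept late samples apart by strain and mixed the 0 min samples. Strains differ in level, which such exchanges turn into a late difference, so none of the 3 decides on chance. For early responses, with labels exchanged within the strain, the real count was highest in wild type (38; highest other 31), rad3 (110; 100) and cds1 (26; 21). In chk1 (60; 702; 2 of 100) the share was under 0.05, but the 702 lay far above the real count. The exchange with 702 genes put all 3 samples of replicate 1 at 0 min, so it follows the replicate number; with that number as a block the count was 408. For late responses the share was under 0.05 in wild type (1203, highest other 1322, 2 of 100) and cds1 (1227, 1204). In rad3 (952; 1188; 6 of 100) and chk1 (1352; 1619; 6 of 100) these exchanges do not decide: of the 5 others as large in each, 3 only exchanged 60 and 120 min labels, which leaves 0 min apart, and 2 put the 120 min samples in place of 0 min. The other as large in wild type also only exchanged treated labels. With both treated times as 1 group and each split counted once, chance can be excluded for late rad3 (1099; highest other 1055; 1 of 56), chk1 (1486; 1500; 2 of 56), wild type (1255; 702; 1 of 56) and cds1 (1189; 795; 1 of 84). The 1500 took the 120 min samples as 0 min. The real count was highest for early wild type (29; 19; 1 of 56) and rad3 (106; 105; 1 of 84). In early cds1 (20; 106; 3 of 84) and chk1 (45; 668; 4 of 84) the share was under 0.05, but the highest other lay far above the real count. Samples with the same number varied together, so exchanges and splits leave early responses open. The 668 again took replicate 1 as 0 min, and the 106 and 668 point to a structure of the samples. Among exchanges that part as many replicate pairs as the real labels, the highest count was 31 for early wild type, 21 for early cds1, 47 for early chk1, 1204 for late cds1 and 1619 for late chk1; among those that part fewer it was 18, 3, 702, 499 and 904. For untreated mutants the 10 splits are too few: rad3 had 47 genes, cds1 6 and chk1 7, with 0 as the highest other in each. The 3 other splits that part as many pairs gave 0, as did the 6 that part fewer, for both cds1 and chk1.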

How the results depend on the processing

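Counts of genes below are in the order early, late, untreated, late difference. The fits with all 70 arrays and with either probe alone were chosen only after the results were seen. Unless a cause is given, it was not tested. Under centred arrays, genes measured on all 70 arrays, no filter on missing values and robust eBayes, each of the 20 counts of changed genes stayed within 1.5 times. Counting a call once for each setting that changed it, settings other than leaving out samples ended calls of named genes 669 times and of lists 151 times, and added calls 335 and 80 times. The number of arrays limits precision. The fits of rad3 sep1 alone left no residual freedom and were not run, nor were fits without a rad3 sep1 sample (its group would vanish) and lists under the random block.

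Under quantile normalization, which gives every array the same set of values, counts were 67 for early wild type, 223 for early rad3, 227 for early chk1, 4 for early rad3 sep1, 116 for late rad3 sep1, 44 for untreated cds1 and 26 for untreated chk1. For late differences they were 49 for cds1, 2 for chk1, 44 for rad3 sep1 from wild type and 6 for rad3 sep1 from rad3. Reversed were psi1 in early wild type (-0.53), late wild type (-0.61), late rad3 (-0.20), late cds1 (-0.38) and late chk1 (-0.43), hsp16 in early chk1 (-0.21), and slp1 (-0.0325), hsp104 (-0.10) and sti1 (-0.24) in late rad3. So were ssa1 in late cds1 (-0.22) and rad3, mutated in both strains, in untreated rad3 sep1 against rad3 (0.89). This setting also removes changes of spread. The SD of wild-type arrays was 0.30 to 0.32 at 0 min and 0.50 to 0.51 at 120 min. Genes already among the highest at 0 min can then hardly rise, so for them it does not decide. For instance hsp16, at 3.45 in untreated rad3, changed by 0 early there. Of lists, chaperone genes reversed in early cds1 (-0.0803), late rad3 (-0.0154), late cds1 (-0.0268) and late chk1 (-0.16), ribosomal protein genes in early rad3 sep1 (-0.0655), and stress (-0.23) and Pap1 genes (-0.0818) in the late difference of rad3. In that of cds1 the stress test turned (median 0.0633).

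With every probe as its own feature counts were 22 for early wild type, 49 for early rad3, 11 for untreated cds1 and 4 for untreated chk1. With only the strains of the comparison they were 13 for early cds1, 33 for early chk1 and 22 for the late difference of rad3 sep1 from rad3. At 1.5-fold or more, which drops smaller changes, they were 15, 27, 8 and 16 for early wild type, rad3, cds1 and chk1, 283, 224, 230 and 309 for the late responses in that order, and 606 and 686 for untreated rad3 sep1 against wild type and rad3.

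Array weights gave 249, 919, 136, 311 and 21 for early wild type, rad3, cds1, chk1 and rad3 sep1, 1917 and 1743 for late wild type and rad3, and 150, 89, 53 and 1591 for untreated rad3, cds1, chk1 and rad3 sep1. Late differences from wild type were 268, 456, 1 and 294 for rad3, cds1, chk1 and rad3 sep1. Against rad3, rad3 sep1 had 1725 untreated and 132 late.

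With the replicate number as a block, early counts were 101, 519, 123, 408 and 36 in the same order, late ones 1572, 1848 and 1241 for rad3, cds1 and rad3 sep1, and untreated ones 43 for cds1 and 1410 for rad3 sep1. Late differences were 266, 414, 1 and 272, and 165 for rad3 sep1 from rad3. As a random block it gave 89, 465, 106, 389 and 31 early, 1465 for late rad3, 11 for untreated cds1, and late differences of 208, 364, 1 and 283, and 130 for rad3 sep1 from rad3. Where numbers did not pair every sample (late wild type, rad3), the block is given only here.

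Without subtracting 0 min, wild type had 2392 early and 3055 late. Reversed early were cds1 (0.28), sep1 (-0.18), bio2 (-0.28), rps2602 (0.19) and rpl1602 (0.57), and histone (0.24) and ribosomal protein genes (0.46), the last also late (0.42). With an estimated correlation 86 of 139 lists passed.

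All 70 arrays as samples gave 87, 267, 47, 178 and 162 early, 1771 for late rad3 sep1, 21 for untreated cds1, 1926 for untreated rad3 sep1 and 2052 against rad3. Late differences were 160, 219, 1 and 494, and 339 for rad3 sep1 from rad3. Counting near-identical arrays as independent shows the cause for rad3 sep1.

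The first probe alone gave 12, 25, 11, 22 and 2 early, 748, 582, 875 and 425 for late wild type, rad3, chk1 and rad3 sep1, 28 and 511 for untreated rad3 and rad3 sep1, and 618 for rad3 sep1 against rad3. Late differences were 52 for cds1, 51 for rad3 sep1 and 6 for rad3 sep1 from rad3, and ctt1 reversed in that of cds1 (-0.0923). The second gave 19, 41 and 15 for early wild type, rad3 and cds1, 725, 561, 880 and 438 late, 31, 1 and 479 for untreated rad3, chk1 and rad3 sep1, and 579 against rad3. Late differences were 41, 67 and 57 for rad3, cds1 and rad3 sep1, and 26 from rad3. On it caf5 reversed in late rad3 (-0.18), late rad3 sep1 (-0.43) and the late difference of rad3 sep1 (-0.19), and rps2802 in late cds1 (-0.0718) and late rad3 sep1 (-0.10).

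In late rad3, sep1 (0.26, adjusted p = 0.0608) passed with centred arrays (0.29), quantile normalization (0.35), array weights (0.24), either block (0.27 and 0.27) and all 70 arrays (0.29). Leaving out 1 sample it ranged from 0.17 to 0.35.

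Leaving out 1 sample, early counts ranged from 21 to 38 in wild type, 24 to 198 in rad3, 13 to 38 in cds1 and 26 to 95 in chk1, and late ones from 730 to 1253, 592 to 996, 875 to 1209 and 943 to 1317. Untreated ones ranged from 29 to 40 in rad3, 3 to 14 in cds1, 3 to 8 in chk1, 685 to 889 in rad3 sep1, and 882 to 974 against rad3. Late differences ranged from 45 to 66, 55 to 147, 0 to 1 and 85 to 116, and 27 to 51 from rad3. The 1 gene for chk1 appeared without replicate 3 of wild type at 120 min or the merged chk1 sample at 60 min. The ribosomal protein median of its late difference ranged from -0.169 to 0.0800, the highest without replicate 1 of chk1 at 60 min, where it reversed.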

Other observations

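The comparisons of strains at later times and with chk1, and of cds1 with rad3, were chosen only after the results were seen; the other tests were planned.

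Between rad3 and wild type at equal times, 53 genes differed at 10 min, 50 at 30 min, 81 at 60 min and 806 at 120 min. At 120 min in rad3, uds1 was higher by 2.76 ± 0.11, slp1 by 2.36 ± 0.12 and eng1 by 2.23 ± 0.14, while str3 was at -2.70 ± 0.16 and cdt2 at -1.71 ± 0.10. At 30 min slp1 was higher by 0.49 ± 0.13 (adjusted p = 0.0446). At 60 min slp1 differed by 0.01 and eng1 by 0.01, and neither passed, while uds1 was higher by 0.55 ± 0.14 (adjusted p = 0.0173). In cds1 against rad3 the late MBF difference was -0.16 (adjusted p = 3.89e-07).

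Stress genes were higher in untreated rad3 than in untreated wild type. Untreated samples that stand apart were argued against by the same difference at 10 and 30 min, at least 0.28. Normalization between arrays was argued against by a difference of at least 0.41 with centred or quantile normalized arrays. With the replicate number as a block the difference was 0.49, but each number occurs once per strain, so the block could not change it and decides nothing on batches. This may reflect a standing stress state of the strain; batches and growth conditions that went with the strain stay open.

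The late differences of rad3 and cds1 from wild type share the wild-type samples. Across genes their r was 0.753, against 0.495 in simulated data with shared controls alone. With no shared samples, rad3 against wild type and cds1 against chk1 had r = 0.551, with 21 genes lower and 8 higher in both. For cds1 against wild type and rad3 against chk1 these were 0.573, 21 and 15.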
